A study of Mus musculus with 15 samples.

How the data were processed

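The series title names the adipocyte factors PPARg and C/EBPa, while the libraries analysed here are ChIP-seq of HSF1 from mouse brown adipose tissue. There are 15 samples: 10 HSF1 ChIP libraries in 5 groups of 2 (wild type at room temperature, a first wild type pair at 40 min of cold, wild type at 4 h of cold, a second wild type pair at 40 min of cold, and TXNIP knockout at 40 min of cold) and 5 input libraries, for which no file was analysed here. Per the labels, tissue was fixed with 2 mM DSG for 25 min and with 0.8% formaldehyde for 12 min, and chromatin was precipitated with Cell Signaling antibody 4356. Inputs were made from 10 ng of material. The condition of 1 input differs between its title and its treatment label, so it was placed in no group.

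Per the submitters' processing notes, the tools were Trim Galore 0.6.0, BWA 0.7.17, SAMtools, MACS2 2.2.7.1 and deepTools 3.4.3, and the genome build was GRCm38.p6 (mm10). Filters, duplicates and which input served which library are not given in the sources used here. The authors deposited a list of narrow peaks for each ChIP library, called on single libraries and not on pooled replicates. Each deposited list gives a fold enrichment per peak, which is a linear ratio of the signal at the summit to the local background, along with the position of the summit. It also gives the −log10 of the p-value and of the q-value of each peak, as the authors' peak caller wrote them, and the smallest −log10 q was 1.30. A further deposited column holds an integer score, which was not used here. The lists hold no read counts, so depth per library is unknown, and the input behind each fold is not known to be the same for all groups. Folds of different libraries are therefore given side by side only as descriptions and were not tested as levels. They served to describe, order and filter peaks within a list, and in 1 comparison to order the same regions within each list.

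Peaks with the same start and end were counted once, and chromosomes 1 to 19, X and Y were kept. Positions are 1-based. Genes were 21887 protein-coding genes of GRCm38 from a table with positions, symbols and synonyms but no strand, so a start could not be told from an end. The distance to a transcription start, fixed in the design, was therefore replaced by the distance from a summit to either end of a gene, and "near a gene end" means within 1000 bp. No genome sequence was used here, so the planned search for heat shock elements, with its alternatives of no mismatch and 250 bp, and the planned filter on repeats were not run.

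Peaks of different libraries that overlapped by at least 1 bp were merged into regions. A region was reproducible when it held a peak of both replicates. A region was gained or lost when both libraries of a group called it and neither library of the other did, and the same count was made in both crossed splits of the 4 libraries. The genotype comparison used the second wild type pair as control, since the time course does not need it. The labels do not say which wild type pair was prepared with the knockout, so the first pair was an alternative. Replicate overlap was set beside 1000 random placements of the peaks on their chromosomes, and gene-end shares beside 100000 random positions with Wilson 95% intervals. Peak numbers were compared by a two-sided exact permutation test on log2 values. Shares were compared by two-sided Fisher's exact tests.

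Gene lists numbered 17: heat shock chaperones and co-chaperones, mitochondrial chaperones and proteases, chaperonin TRiC subunits, endoplasmic reticulum chaperones, proteasome subunits, ubiquitin and proteotoxic stress genes, thermogenic brown adipocyte genes, general adipocyte genes, TXNIP, thioredoxin and glucose uptake genes, respiratory chain subunits, immediate early genes, clock genes, cytosolic ribosomal proteins, markers of skeletal muscle, endothelium and leukocytes, and olfactory and vomeronasal receptors as a silent control. Of 366 listed symbols, 360 matched by symbol or by a single synonym. Older and newer names of the same ATP synthase and clock genes were both listed and counted once. Each list was tested in each group by a one-sided Fisher's exact test (greater) against all other genes, with Benjamini-Hochberg adjustment over lists and groups. Members gained or lost were tested by two-sided Fisher's exact tests against the other genes that could change, adjusted over lists and both directions within a comparison. Genes that could be lost had a peak near an end in both libraries of the first group, and genes that could be gained had one in neither. This background was chosen after seeing the data. The groups, most tests, the gene lists, naming rule and most alternatives were fixed before the data were examined.

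The naming rule took 16 genes in every group (9 chaperone genes, Bag3, Txnip, Ucp1, Ppargc1a, Dio2, Pparg and Cebpa). It also took, per comparison and direction, up to 10 genes within 1000 bp of a gained or lost region and the 5 regions leading at any distance, ordered by the worse of the 2 relative ranks by −log10 p, and the 5 leading regions of each group. List members are named with their list. Some genes that the rule takes are not reported here.

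Alternatives were a −log10 q of at least 5, peaks narrowed to 200 bp around the summit, a reciprocal overlap of 50%, an equal number of top peaks by −log10 p in each library (the length of the shortest list compared), peaks of either replicate, a 5000 bp window, all sequence names, the other wild type control and leaving out each replicate in turn. Equal numbers of top peaks for list members were added after seeing the data. The order of the same regions was measured by Spearman correlation of folds over regions called in all 10 libraries, with 1000 bootstrap resamples of regions. Tests of the change of place by class of site were left out, since a region had to be called at 4 h to have a place. The counting of gained and lost regions and the list test were tested on simulated data: in 100 simulations of the room temperature to first 40 min comparison, with 600 shared, 400 gained and 100 lost regions, 100% of gained and lost regions were found. Each simulated region was called in every library meant to hold it. The simulations thus check the counting and do not show how many regions are found when a replicate misses a peak. Over 21887 genes, lists of 30 genes with 20 peaks passed in 100% of the simulations and random lists in 0%. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.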

Results

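Heat shock factor 1 (HSF1), the transcription factor that activates chaperone genes under proteotoxic stress, was mapped by ChIP-seq in mouse brown adipose tissue (BAT), the fat depot that burns fuel for heat in the cold. The series has 10 HSF1 ChIP libraries in 5 groups of 2. Wild type mice were sampled at room temperature, after 40 min of cold and after 4 h of cold. There is also a second pair of wild type libraries at 40 min of cold, and 2 libraries come from mice labelled as TXNIP knockouts at 40 min of cold. The titles of the second pair repeat the replicate numbers of the first with a suffix. Whether both pairs come from the same samples is not stated. TXNIP is a thioredoxin-binding arrestin that restrains glucose uptake. The 2 libraries of a group are not stated to come from separate animals, so the permutation test on peak number measures only the spread between libraries, which may be technical. All other p-values compare genes, peaks or regions and carry no measure of the spread between libraries or animals. Read depth is unknown, since each library is represented by a peak list without counts. Fold enrichments and −log10 p values per peak are the authors' own, and they serve here only to describe and order peaks within a list.

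HSF1 peak lists differed widely in length between groups. Room temperature libraries held 919 and 1269 peaks on the standard chromosomes (mean 1094 ± 247, SD, n = 2), and the first pair at 40 min held 2287 and 1670 (mean 1979 ± 436, SD, n = 2). The lists at 4 h were the shortest, with 123 and 351 peaks (mean 237 ± 161, SD, n = 2). The second wild type pair at 40 min had 12644 and 14583 peaks (mean 13614 ± 1371, SD, n = 2), and the libraries labelled TXNIP knockout had 10399 and 10633 (mean 10516 ± 165, SD, n = 2). The longer list of a pair held 1.02 to 1.38 times the peaks of the shorter one outside 4 h and 2.85 times at 4 h, a wider gap than the 1.81-fold difference between room temperature and the first 40 min pair. With 2 libraries against 2, a two-sided exact permutation test cannot give a p below 0.33, and each of the 5 comparisons of log2 peak number gave that smallest p.

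**Figure D1:**
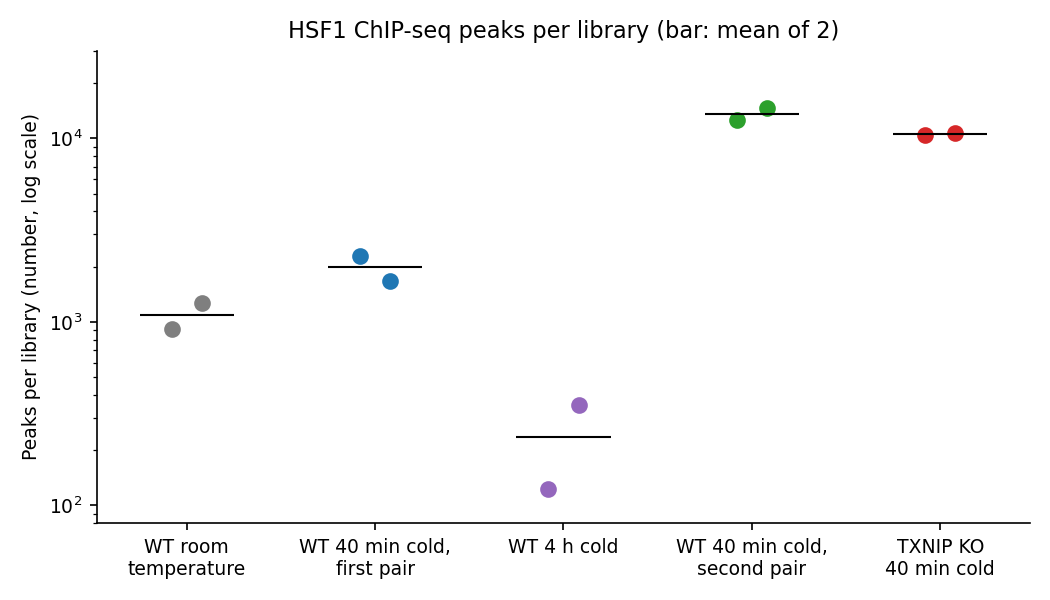
HSF1 peaks per library on a log axis, with 1 point per library and a bar at the mean of the 2 libraries of each group. The 4 h lists (123 and 351 peaks) lie lowest and those of the second wild type pair at 40 min (12644 and 14583) highest.

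Most peaks of the shorter list of each pair were found by its replicate. Of the peaks in the shorter list of a pair, 87.4% overlapped a peak of the other replicate at room temperature, 89.3% in the first 40 min pair, 87.8% at 4 h, 83.4% in the second 40 min pair and 77.7% in the knockout, against at most 1.16% in any of 1000 random placements. Of the peaks in the longer list, 63.1%, 64.9%, 30.8%, 71.5% and 76.0% did, so most peaks of 4 h replicate 2 were not found by replicate 1. Such overlap was not particular to a pair, and it also depends on the length of the other list. Of knockout replicate 1 peaks, 82.8% and 87.0% overlapped the longer second pair lists, against 77.7% for its own replicate. Of second pair replicate 1 peaks, 83.4% overlapped its own replicate, and 68.4% and 68.7% the knockout lists. Regions with a peak in both replicates numbered 801, 1483, 108, 10367 and 8004 in the same order. Sites lay near gene ends far more often than random positions: 27.3% of regions at room temperature, 21.8% in the first 40 min pair, 44.4% at 4 h, 25.6% in the second 40 min pair and 23.4% in the knockout had their summit within 1000 bp of either end of a protein-coding gene, against 2.87% of random positions. At 4 h the share was 24.5% without replicate 1 and 39.8% without replicate 2. At room temperature, the strongest of 4 equal parts of the list by −log10 p was near a gene end more often than the weakest, with 43.2% against 22.7% in replicate 1 and 36.0% against 22.1% in replicate 2. The order was the opposite in the long lists. In the second 40 min pair 18.98% of the strongest and 38.4% of the weakest part lay near a gene end in replicate 1, and in knockout replicate 2 the shares were 20.9% and 36.4%. All 10 lists gave a difference between these parts (adjusted p of 0.0352 or lower, two-sided Fisher's exact test over peaks, which are not replicates).

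The HSF1 peak at the mitochondrial chaperonin genes was among the strongest of each group. A single region between Hspd1 and Hspe1, which encode this chaperonin and its cofactor (chromosome 1, summit 55088031 in GRCm38), ranked first in 8 of 10 libraries and second in both 4 h libraries, with folds of 194 and 193 at room temperature, 400 and 328 in the first 40 min pair, 53.6 and 117 at 4 h, 1296 and 1210 in the second pair and 1148 and 1109 in the knockout. Peaks near Uspl1, Dnaja1, Hsp90ab1 and St13 were among the other leading ones at room temperature, and those near Uspl1, Dnaja1 and Hsp90ab1 at 40 min. Dnaja1 and Hsp90ab1 encode an HSP40 and an HSP90 chaperone, and St13 an HSP70 partner. At 4 h, the region with the best worse rank lay at chromosome 2, position 98666980, 1035308 bp from the nearest gene end (Lrrc4c), with folds of only 3.01 and 4.91. Hspe1, the region between Xpnpep3 and St13, and Hspa8 were also among the 5 leading regions. Hspa1a, Hspa1b, Hspa8, Hsph1, Hsp90aa1, Hsp90ab1, Dnajb1, Hspd1 and Hspe1 had a peak within 1000 bp of a gene end in 10 of 10 libraries. Bag3, a partner of HSP70 in selective autophagy, had one in 9 and none in 4 h replicate 1. Hspa1a and Hspa1b are near-identical copies, so which of them a read came from is uncertain. At room temperature 17 of 23 chaperone peaks (73.9%) in replicate 1 and 79.2% in replicate 2 stood among the strongest 5% of their list. At 4 h, where that part of a list holds fewer peaks than there are chaperone peaks, 1 of 16 in replicate 1 and 7 of 19 in replicate 2 did.

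HSF1 peaks within 1000 bp of a gene end were found in 0 of 10 libraries for Ucp1, the uncoupling protein of brown fat, Ppargc1a, the coactivator of mitochondrial biogenesis, and Dio2, the thyroid hormone deiodinase. Near Ucp1, 5 libraries had a summit within 5000 bp, and no peak lay in or near Dio2. Ppargc1a had a peak inside the gene, 53302 bp from its end and at chromosome 5, position 52062551, in second pair replicate 1. The gene held a peak in 9 libraries, with highest folds of 5.96 and 7.61 at room temperature, 15.2 and 21.7 in the first 40 min pair, 69.7 and 72.9 in the second pair and 56.2 and 65.0 in the knockout, and at 4 h only in replicate 2 (4.3). Pparg, the adipocyte nuclear receptor, had a peak in or near the gene in 4 libraries, all from the second pair or the knockout, and Cebpa in 1 knockout library.

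Across the 17 gene lists, heat shock chaperones and co-chaperones stood out everywhere. Of 30 members, 23 had a peak of both replicates near a gene end at room temperature (adjusted p = 2.86e-37), 24 in the first 40 min pair (3.23e-36), 16 at 4 h (2.44e-33), 24 in the second 40 min pair (5.26e-15) and 25 in the knockout (7.40e-20; one-sided Fisher's exact tests against all other genes, which are not replicates). All 8 subunits of TRiC, the cytosolic chaperonin, were bound in every group except 4 h, where Cct3, Cct4 and Cct8 were. Mitochondrial chaperones and proteases had 3, 3, 2, 6 and 5 of 14 members bound in the 5 groups and passed the test in each, with Hspd1 and Hspe1 in all. These genes share a single region, so the 2 members at 4 h rest on 1 peak counted for both. Endoplasmic reticulum chaperones passed in 4 groups with 3, 3, 9 and 7 of 16 (Hsp90b1, Canx and Pdia3 in each of these 4). At 4 h none had a peak of both replicates, while 2 had a peak of a single replicate. Ubiquitin and proteotoxic stress genes passed at room temperature with 2 of 14 (adjusted p = 0.0317, Fisher's exact test), at 4 h with 2 (0.00275) and in the second pair with 6 (0.0214), but not with 1 in the first 40 min pair (0.430) or 4 in the knockout (0.0979).

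Lists outside proteostasis passed mainly in the long peak lists, in which 2973 (second pair) and 2120 (knockout) of 21887 genes had a peak. The background was all other genes, whether active in the tissue or not. In these long lists the weakest peaks lay near gene ends more often than the strongest. A list of active genes may thus pass through weak peaks, and passing does not show its members to be HSF1 targets. Immediate early genes had 16 of 27 members bound in the second 40 min pair and 14 in the knockout (adjusted p = 3.23e-07 for each, Fisher's exact test), 3 in the first 40 min pair (0.0294), 2 at room temperature (0.0979) and 0 at 4 h. TXNIP, thioredoxin and glucose uptake genes had 9 and 8 of 19 (0.00219 and 0.00132), including Txnip, Slc2a4, the insulin-responsive glucose transporter, and Txn1. General adipocyte genes had 10 and 8 of 30 (0.0161 and 0.0209), including Plin1, Cidec, Pck1 and Lpl. Respiratory chain subunits passed only in the second pair, with 11 of 34 (0.0143), as did cytosolic ribosomal proteins with 11 of 31 (0.00680). Proteasome subunits (5 and 1 of 31 in these 2 groups) and clock genes (5 and 2 of 18) did not pass. Thermogenic genes did not either, with 3 and 3 of 28 (Ppara, Cidea and Esrra in both). Within 5000 bp of a gene end, 13 and 13 thermogenic genes had a peak and passed (0.00716 and 7.25e-04). Markers of other cells in the depot did not pass in any group: skeletal muscle genes had at most 2 of 16, endothelial genes 3 of 13 and leukocyte genes 0 of 14. Of 17 olfactory and vomeronasal receptors, the silent control list, 1 had a peak in each of these 2 groups and 0 elsewhere.

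**Figure D2:**
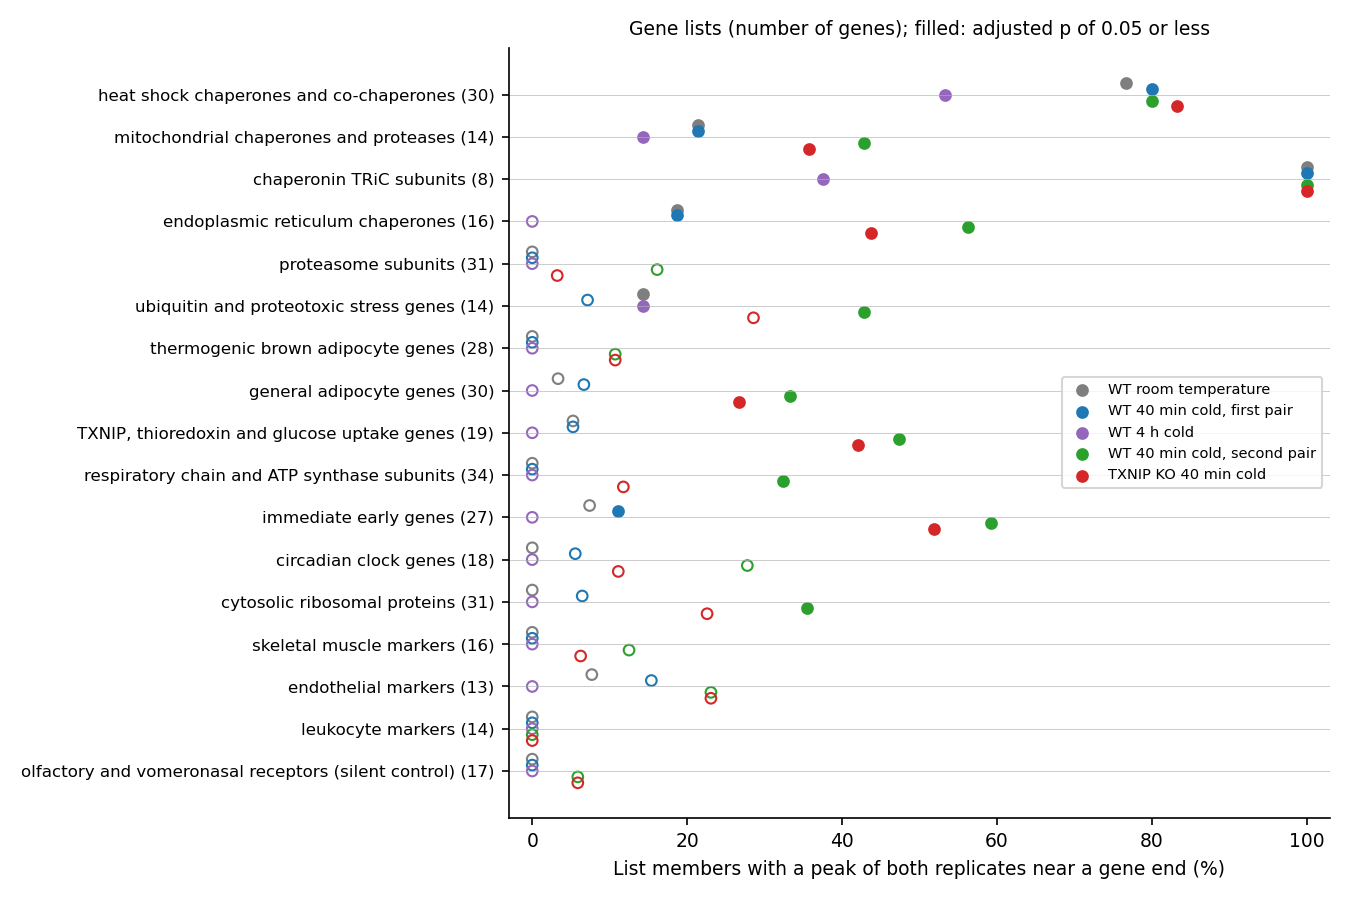
Share of each gene list (rows, number of genes in brackets) with a peak of both replicates within 1000 bp of a gene end, in percent, with 1 point per group and filled points for an adjusted p of 0.05 or less (one-sided Fisher's exact test). Heat shock chaperones lie between 53.3% and 83.3% in all groups, and leukocyte markers stay at 0.

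The first question of the time course is where HSF1 peaks appear within 40 min of cold. HSF1 peaks were gained, and few were lost, from room temperature to the first 40 min pair. The room temperature sites were nearly all kept: 99.4% of the regions called there overlapped a 40 min peak, and 756 regions were called in all 4 libraries. A further 409 regions were called in both 40 min libraries and in neither room temperature library, and 5 the other way. Mixed splits of the same 4 libraries gave totals of 50 and 89 against 414. Such splits set a longer and a shorter list on each side, so they tend to give fewer regions. In full lists they therefore do not separate an effect of cold from list length. The wild type pairs, both at 40 min, gave 7990 against crossed totals of 3 and 2. The same limit holds for each comparison of full lists below. Gained regions lay mostly away from gene ends, with 12.7% near one against 28.3% of shared regions (adjusted p = 3.50e-09, two-sided Fisher's exact test). The strongest gained regions were 2928 bp from Depp1, 7874 bp from Ctif and 27484 bp from Gmpr, with folds of 16.7 and 17.1, 16.4 and 15.9, and 19.3 and 14.2 in the 2 libraries.

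Among gained regions near a gene end, the best placed were at Rhou (folds 11.4 and 9.46), Tubgcp4, Mboat2 (7.97 and 9.46), 1700007K13Rik, Traf6, A930018P22Rik, Atf1, a transcription factor of the CREB family (10.6 and 8.23), Pafah2, Slc35f5 and Mmrn2. Pik3r2 was the only such gene among the lost regions (4.92 and 5.05). Chaperones were already bound at room temperature, and only Dnajb6 among the 30 gained a peak. Crem, Rpl15, Rps18 and Flt1 were the other list members gained, and no list passed against the other genes without a room temperature peak (adjusted p of 0.100 or higher, two-sided Fisher's exact test). The gained count depends on list length. With the 919 strongest peaks of each library, 94 regions were gained and 57 lost, against crossed totals of 31 and 40, and 9.57% of the gained regions lay near a gene end against 29.7% of shared ones (adjusted p = 3.99e-05, Fisher's exact test). Lost regions lay near a gene end in 17.5% of cases, and gained and lost regions did not differ detectably (p = 0.205, Fisher's exact test). With 1 library standing for its group, 681 regions were gained without room temperature replicate 2 and 1058 without 40 min replicate 2, and 93, 32, 41 and 8 were lost without room temperature replicates 1 and 2 and 40 min replicates 1 and 2.

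**Figure D3:**
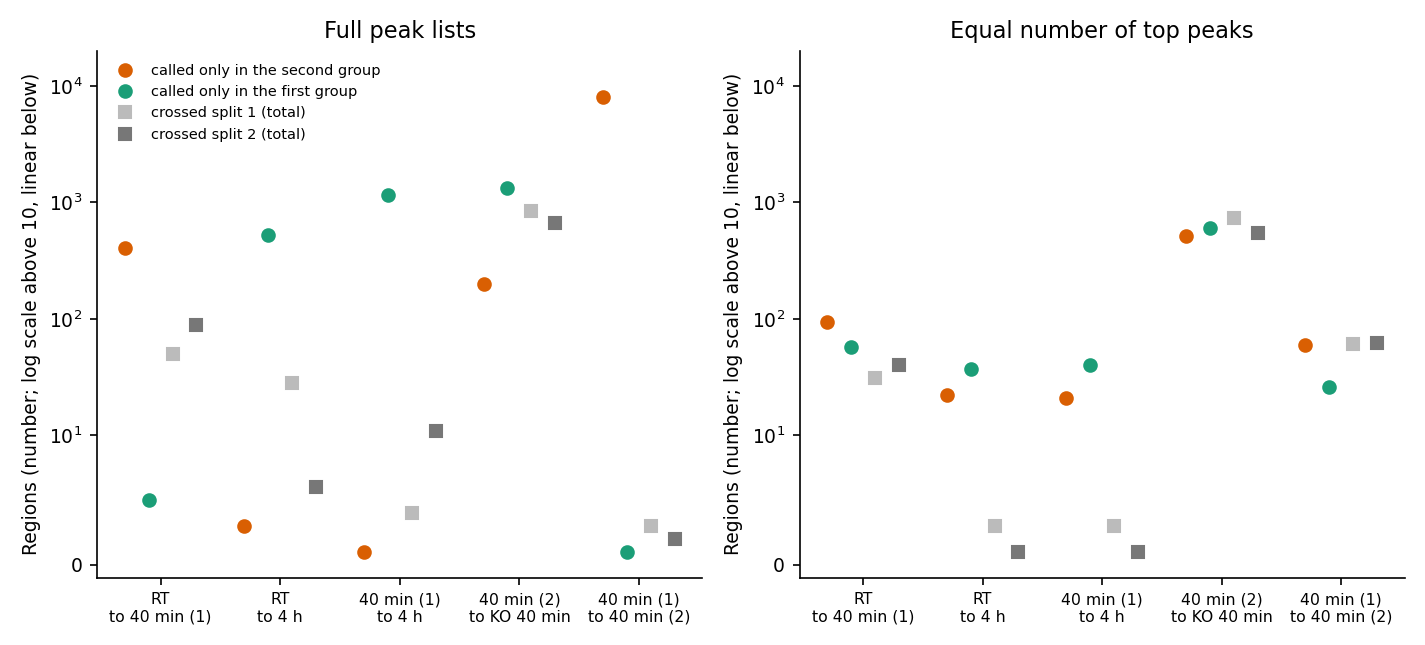
Regions called in both libraries of a group and in neither of the other (circles) and the totals of the 2 crossed splits of the same 4 libraries (squares), for full lists and for equal numbers of top peaks, on an axis that is logarithmic above 10; (1) and (2) are the first and second wild type pairs at 40 min. In full lists the 4 h group lost 522 regions from room temperature and 1148 from 40 min; with equal lists it lost 37 and 40 and gained 22 and 21.

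The second question is what remains of HSF1 binding after 4 h of cold. Most room temperature sites were no longer called at 4 h, while heat shock chaperone genes kept their peaks more often than other bound genes. Of 525 regions that separated the groups, 522 were lost and 3 gained, against crossed totals of 28 and 6. Nearly all 4 h regions (97.2%) were room temperature sites, while 34.9% of room temperature regions were still called. Lost regions near a gene end were led by Kctd18 (folds 37.2 and 46.5 at room temperature), Swt1 (21.2 and 24.2), Hspbp1, an exchange factor for HSP70 (18.3 and 20.7), and Jun, a subunit of the AP-1 factor (24.1 and 16.2), followed by Cct5, Castor1, Cct6a, Zfp526, Fxr1 and Dnajb2. Of 23 chaperones bound at room temperature 4 were lost (17.4%), namely Dnajb2, Hspa4, Dnajb4 and Hspb8. Of 236 other bound genes 66.5% were lost (adjusted p = 1.94e-04, two-sided Fisher's exact test). Chaperone peaks were also the stronger ones at room temperature, with median folds of 66.3 and 61.8 against 6.91 and 6.64 for other peaks. The test was not matched on fold, so the lower loss cannot be told apart from peak strength. TRiC lost 3 of 8 subunits (Cct2, Cct5 and Cct6a) and did not differ detectably from other bound genes (adjusted p = 1, Fisher's exact test). The 3 gained regions lay away from gene ends, 11950 bp from Tbl1xr1, inside Nisch at 5984 bp from its end and inside Lamc1 at 38215 bp from its end. Without room temperature replicate 1, 951 regions were lost. Gained regions numbered 9 without room temperature replicate 2 and 35 and 12 without 4 h replicates 1 and 2.

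With lists of equal length, regions entered as well as left at 4 h, since a fixed length makes room for others where some leave. These counts describe a change of order by strength and do not show whether binding was lost. Among the 123 strongest peaks of each library, 22 regions entered at 4 h and 37 left, with 57 in all 4 libraries and crossed totals of 3 and 1. None of the 22 entering regions was near a gene end, against 17 of 37 leaving (45.9%) and 42 of 57 shared regions (73.7%), and entering and leaving regions differed (p = 6.67e-05, two-sided Fisher's exact test). Genes nearest to the entering regions, named after the values were seen, included Lifr, Ebf1, Dusp16 and Insr, at 79506, 40253, 4128 and 38765 bp. Leaving regions included those at Ptges3, Ahsa1 and Bag3, 3 co-chaperone genes. They were 3 of 19 chaperones in the room temperature lists (15.8%), against 26.7% of other genes there (adjusted p = 1, Fisher's exact test), so the lower loss of chaperones was not detected in lists of equal length. No TRiC gene left. Of the entering regions 20 of 22 had a peak in a full room temperature list, and 24 of 37 leaving regions still had one at 4 h. Without 4 h replicate 2, full lists gave 7 lost chaperones (Ptges3, Ahsa1 and Bag3 in addition) and 5 lost TRiC subunits.

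The order of the same sites by fold differed at 4 h as well, in a comparison chosen after the values were seen. Of the 100 strongest regions of the second 40 min pair, 58 were called in all 10 libraries, so each library orders the same 58 regions. Dusp6, a MAP kinase phosphatase, moved from mean place 50.5 at room temperature to 13.8 at 4 h, Trafd1 from 52 to 18.8, Per2, a clock gene, from 26.5 to 8.25 and Mat2a, which makes S-adenosylmethionine, from 29.5 to 12.5. Chaperone sites went both ways. Ahsa2 went from place 13 to 43.3, Hspa1a from 11 to 35.5 and Dnajb1 from 34.8 to 52.3, while Hspa8 went from 9 to 4.5, Fkbp4 from 13.5 to 11 and Hsp90ab1 stayed at 6.5. Of 16 such sites 11 moved down, 3 up and 2 not at all. The decline was not particular to chaperones, since of 25 other sites near a gene end 17 moved down and 7 up. Of 17 sites farther away 4 moved down and 13 up. A site had to be called at 4 h to have a place, and of the 100 regions 17 of 39 farther than 1000 bp from a gene end and 41 of 61 nearer ones were called in both 4 h libraries, so the places do not show how either class moved as a whole. Across these regions, which are not independent replicates, the mean rank correlation between room temperature and 4 h libraries was 0.546, against 0.978 within room temperature and 0.883 within 4 h. Between room temperature and the first 40 min pair it was 0.944.

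**Figure D4:**
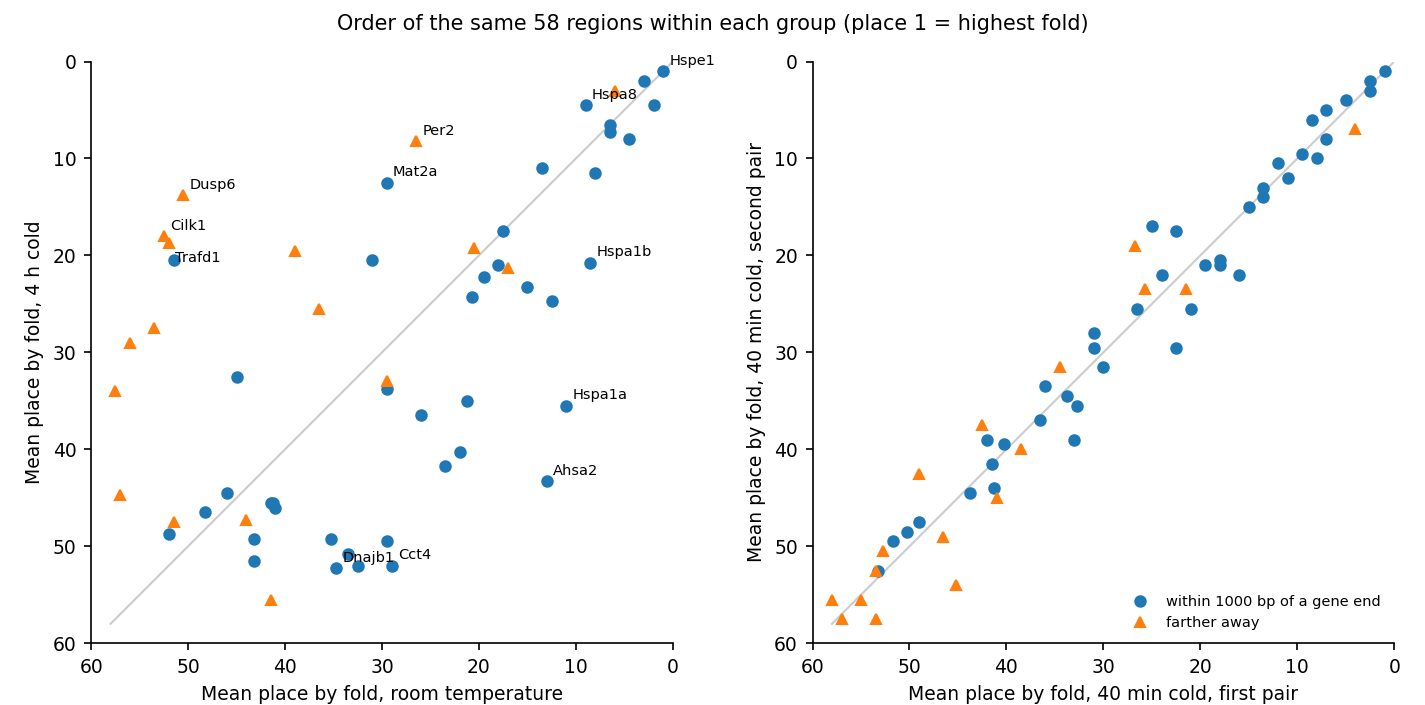
Mean place by fold of the same 58 regions (place 1 is the highest fold) at room temperature against 4 h of cold, and in the first against the second wild type pair at 40 min; circles are regions within 1000 bp of a gene end and triangles those farther away. Regions such as Dusp6 (50.5 to 13.8) and Hspa1a (11 to 35.5) leave the diagonal at 4 h, whereas both 40 min pairs lie along it.

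From 40 min to 4 h of cold most sites were again no longer called. HSF1 regions at Kctd18 (folds 63.8 and 47.9 at 40 min), Dynll1, a dynein light chain (26.6 and 26.2), Mrfap1 (39.0 and 27.0), Castor1, an arginine sensor of the mTORC1 pathway (38.4 and 24.5), Dnajb2, Hikeshi, which imports HSP70 into the nucleus (30.4 and 22.7), Swt1, Hspbp1, Chrac1 and Gm20346 led the lost ones near a gene end. In all 1148 regions were lost and 1 was gained, against crossed totals of 4 and 11, and 22.6% of the 40 min regions were still called. The gained region lay 273 bp from Pgk1, a glycolytic enzyme (chromosome X, 106186723 to 106187235), with folds of 31.7 and 5.71 at 4 h. It was also called at 40 min in the second wild type pair (5.97 and 5.66) and in the knockout (3.73 and 5.53). Room temperature replicate 2 held it too (6.25), so it was missing only relative to the first 40 min pair. Of 24 chaperones bound at 40 min 5 were lost (20.8%), namely those lost from room temperature and Dnajb6. Of 346 other bound genes 77.2% were lost (adjusted p = 1.16e-06, two-sided Fisher's exact test). This test was not matched on fold either, and chaperone peaks at 40 min had median folds of 97.4 and 83.9 against 7.01 and 7.79 for other peaks. TRiC lost the same 3 of 8 (adjusted p = 0.564, Fisher's exact test), and immediate early genes all 3 that were bound (Crem, Jun and Zfp36; adjusted p = 1). Lost regions were near a gene end less often than shared ones (20.8% against 43.8%, adjusted p = 2.40e-06, Fisher's exact test). With 123 peaks per library, 21 regions entered and 40 left, with 1 of 21 and 12 of 40 near a gene end (p = 0.0244, Fisher's exact test). No TRiC gene left, and 3 of 19 chaperones did (15.8%), against 18.5% of other genes in the 40 min lists (adjusted p = 1, Fisher's exact test). In full lists, 1939 regions were lost without 40 min replicate 2, and 8 chaperones and 5 TRiC subunits without 4 h replicate 2. Gained regions numbered 2 without 40 min replicate 2 and 5 and 8 without 4 h replicates 1 and 2.

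The genotype comparison asks how HSF1 binding at 40 min of cold differs without TXNIP. Txnip itself (chromosome 3, 96557957 to 96561857) was first examined as a check of the labels. Peaks covered 2483 and 2975 of its 3901 bp in the second wild type pair and 3228 and 1944 bp in the libraries labelled TXNIP knockout. The deleted part is not given in the sources used here, so peaks cannot settle the label. The covered stretches go against a loss of the whole gene in all cells of the tissue and leave a smaller deletion open. A peak about 6.6 kb before the lower coordinate of Txnip had folds of 55.2 and 53.0 in the second wild type pair, 39.7 and 48.0 in the knockout libraries, 12.1 and 12.8 in the first 40 min pair and 6.59 and 6.90 at room temperature, and was not called at 4 h.

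**Figure D5:**
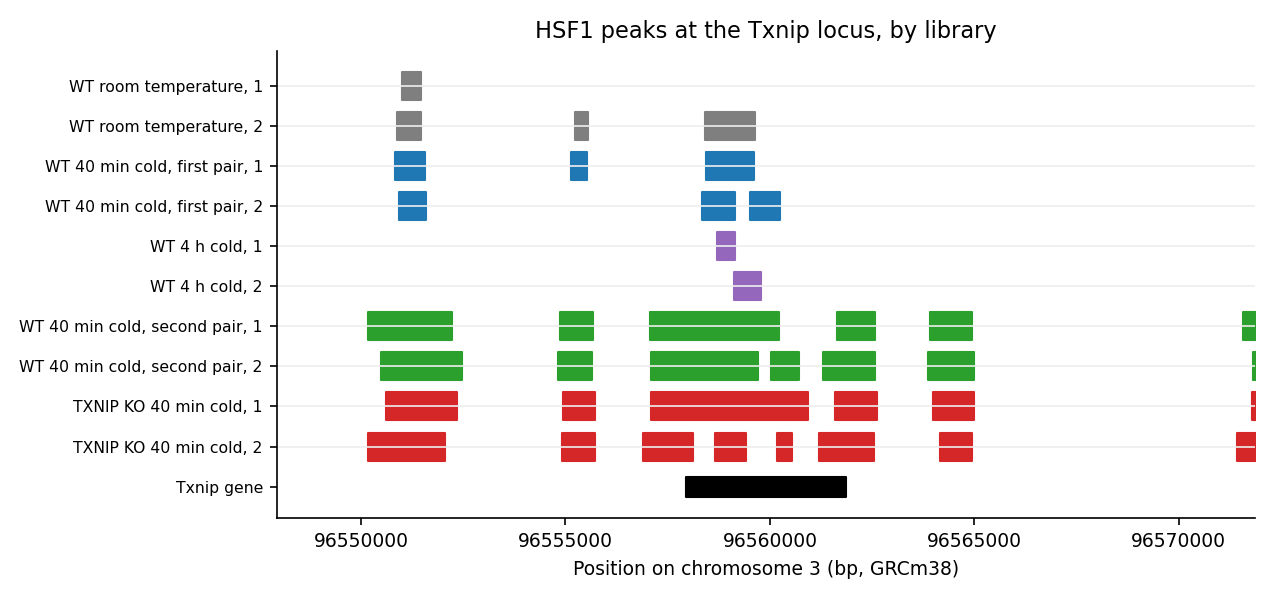
HSF1 peaks of each library (coloured bars, 1 line per library) within 10000 bp of Txnip (black bar), by position on chromosome 3 in bp. The libraries labelled TXNIP knockout have peaks over the gene (3228 and 1944 bp of it covered), as do those of the second wild type pair (2483 and 2975 bp).

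HSF1 sites were largely shared between the libraries labelled TXNIP knockout and the second wild type pair, and more were lost than gained. In all, 7131 regions were called in all 4 libraries, 97.5% of knockout regions overlapped a wild type peak and 87.1% of wild type regions a knockout peak. Chaperone and TRiC genes kept their peaks, with 0 members lost from either list. Regions called only in the wild type pair numbered 1335 and only in the knockout 199, against crossed totals of 850 and 662. Without wild type replicates 1 and 2 and knockout replicates 1 and 2 in turn, lost regions numbered 4020, 2764, 2241 and 2301 and gained ones 383, 643, 917 and 899. The 199 gained regions were fewer than single directions of the crossed splits gave (591 and 425). Lost regions were weak, with a median fold in the lower replicate of 3.78 against 6.37 for those kept. They were near a gene end more often than shared ones (33.0% against 23.6%, adjusted p = 1.77e-11, Fisher's exact test). Weak peaks of these wild type lists lay near gene ends more often than strong ones in any case. In the weakest of 4 equal parts by −log10 p the share was 38.4% in replicate 1 and 35.5% in replicate 2. The test was not matched on strength, so the higher share of lost regions cannot be told apart from their weakness.

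Respiratory chain and ATP synthase genes lost their peak in the knockout libraries more often than other bound genes in full lists. Of 11 members bound in wild type 7 lost it: Uqcrfs1, Sdha, Atp5a1, Ndufs3, Sdhb, Ndufa4 and Ndufa5, which encode subunits of the electron transport chain and, for Atp5a1, of ATP synthase (63.6% against 16.5% of 2962 other bound genes, adjusted p = 0.0209, two-sided Fisher's exact test). Without wild type replicate 1 and without knockout replicate 1 the list did not pass (0.316 and 0.0843). Endoplasmic reticulum chaperones lost 3 of 9 (Pdia4, Herpud1 and Manf) and immediate early genes 3 of 16 (Klf6, Klf4 and Fosb), and neither passed (adjusted p = 1 for each, Fisher's exact test). Lost regions near a gene end were led by Pcdh1, Phgdh, the first enzyme of serine synthesis, Abra (folds 6.37 and 6.69 in wild type) and Ephb4 (6.36 and 5.99), followed by Cyct, Sod3, Cldn22, Gcnt7, Ghr and Ldb3. The 46 gained regions near a gene end were led by Zfp563 (5.39 and 4.74 in the knockout), Trappc6b (4.77 and 4.54), Lgals7 (9.54 and 4.15), Marchf3, Idh3a, an enzyme of the citrate cycle (4.36 and 3.95), Wdr61, Wdr92, Tgfbrap1, Pdlim5 and H4c3.

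The genotype counts rest on list length and on the control chosen. With 10399 peaks per library, 599 regions were lost and 517 gained. Their total of 1116 was 1.53 times the higher of the crossed totals of 729 and 542. The share near a gene end turned round, to 32.9% of gained and 18.9% of lost regions (p = 9.58e-08, Fisher's exact test). The respiratory chain loss was then 3 of 6 bound genes (Ndufs3, Sdhb and Ndufa4) against 6.23% of other bound genes, a ratio no smaller than in full lists that missed the threshold with fewer genes (adjusted p = 0.145, Fisher's exact test). It also missed it at a −log10 q of at least 5, with 4 of 7 genes against 15.0% (0.424), and in a 5000 bp window, with 5 of 20 against 12.7% (1), and no member was bound in both libraries of the first wild type pair. Against that pair, 5630 regions were gained and 1 lost.

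The second wild type pair at 40 min held nearly every site of the first and many more. HSF1 regions of the first pair were found again in 99.9% of cases, and 7989 regions were called only in the second pair and 1 only in the first, against crossed totals of 3 and 2. New regions near a gene end were led by Ywhag, a 14-3-3 protein (folds 24.9 and 28.0), Col8a2 (23.9 and 19.1), Nelfa, a subunit of the pausing complex NELF (21.7 and 19.2), Etfa, an electron transfer flavoprotein subunit (20.1 and 23.3), Msi2, Mrpl45, Cidec, a lipid droplet protein (16.1 and 18.9), C1ql1 and Clec14a. Of the genes with no peak near an end in the first pair, immediate early genes gained 11 of 22, among them Fos, Atf3, Nr4a1 and Dusp1, against 11.3% of other genes (adjusted p = 2.72e-04, two-sided Fisher's exact test). Respiratory chain subunits gained 11 of 34 (0.0153), endoplasmic reticulum chaperones 6 of 13 (0.0198), ribosomal proteins 9 of 29 (0.0305), general adipocyte genes 8 of 27 (0.0457) and ubiquitin and proteotoxic stress genes 5 of 12 (0.0457). Without second pair replicate 1 the endoplasmic reticulum list did not pass (0.0739), without second pair replicate 2 the ribosomal (0.114), adipocyte (0.0715) and ubiquitin (0.0961) lists did not, and without first pair replicate 2 the ubiquitin list did not (0.0549). No list member lost a region near its end. For Lipe, the hormone-sensitive lipase, a peak of the second pair overlapped that of the first without a summit within 1000 bp of the gene end. The region found only in the first pair lay inside Slc2a1, which encodes the glucose transporter GLUT1 (folds 3.62 and 6.68). Without second pair replicate 1, 12202 regions were gained, and 7 and 11 were lost without first pair replicates 1 and 2. With 1670 peaks per library, none of these lists gained a member except the adipocyte list (Cidec), 60 and 26 regions were specific to the second and first pair and the crossed totals were 61 and 62, and the same 58 strong regions kept their order (mean rank correlation 0.972).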

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

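The tests in this part were chosen after the results were seen. For respiratory chain genes against matched genes, the prediction was written before that test was run, but for a loss already seen. Of the equal-length lists, only the counts of gained and lost regions were planned, without the limits they are held to here.

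HSF1 peaks on sequences outside the standard chromosomes, which no comparison uses, numbered 47 over the 10 libraries. Of these, 34 lay on the unplaced scaffold JH584304.1, in 10 of 10 libraries and so in every group.

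At 4 h of cold, HSF1 peaks were fewest and the order of folds among the same regions differed from that at room temperature. A single factor of depth or enrichment would shorten the list and, apart from noise, leave the order of the same regions as it was. The rank correlation between room temperature and 4 h was 0.588 of that within the groups (95% interval 0.363 to 0.771), against 0.965 (0.920 to 0.987) between room temperature and 40 min. The 58 regions had to be called at 4 h, however. Intervals also stayed short of equality for room temperature to 40 min and for the second pair to the knockout (0.978, 0.946 to 0.995). Noise weighs more where folds are low, and in 4 h replicate 1 Cct3 and Dnajb1, for example, shared a fold of 5.97. Noise of an input, if shared by both 4 h libraries, would not be removed by dividing by the correlation within 4 h. The lower ratio at 4 h thus shows a different order for these regions and does not decide whether such a factor alone gave it. Background regions would not rank high by fold in lists that did not choose them, yet 86.4% of the regions entering the equally long 4 h lists (19 of 22, Wilson 95% interval 66.7% to 95.3%) were among the strongest 10% by fold in both libraries of the second 40 min pair. What stays open is such a common factor, in full or in part, and a different input or local background for each group, which the lists cannot show. A change of HSF1 binding with time in the cold stays open as well.

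The second wild type pair at 40 min had 6.95 times as many peaks as the first, by geometric means. With equally long lists, regions specific to a pair were 1.39 times the higher crossed total, and the order of strong regions had a ratio of 0.990 (95% interval 0.974 to 1.001). Both are consistent with 1 common factor of depth or enrichment, and no biological explanation was tested, since the labels give both pairs the same treatment. Respiratory chain, ribosomal protein and general adipocyte lists passed only in the second pair or the knockout, so their absence from the shorter lists may be a matter of detection.

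More regions were lost than gained in the libraries labelled TXNIP knockout, but with equally long lists the lost regions were 1.16 times the gained ones, so the difference in list length may account for the excess. It was not shown to account for all differences. Regions specific to a group were then 1.53 times the higher crossed total, against 1.39 between the wild type pairs. The order of strong regions had a ratio of 0.978 (95% interval 0.946 to 0.995). Only 127 wild type regions lay within 10000000 bp of Txnip, too few to give the excess of lost regions whatever share of them was lost. A chromosome segment there that differs between strains therefore does not account for it. Of these regions 12.6% were lost (16 of 127, Wilson 95% interval 7.91% to 19.5%), against 12.9% elsewhere (p = 1, Fisher's exact test). A strain difference elsewhere in the genome was not tested. For the respiratory chain loss in full lists, 7 of 11 bound genes lost their peak, against 2.28 of genes matched on wild type fold (one-sided Monte Carlo analogue of a permutation test, 100000 draws of matched genes, p = 5.90e-04). The list was taken up because it had passed in the same libraries, so this p carries that selection and is not separate support. Lost genes had lower wild type folds of 2.92 to 4.58. Of the kept genes, Cycs (7.70), Atp5b (5.83) and Atp5c1 (4.80) lay above that range and Ndufs1 (3.94) within it. Weak wild type peaks are therefore not excluded. In equally long lists 3 of 6 bound genes lost their peak against 6.23% of other bound genes, short of the threshold (adjusted p = 0.145, Fisher's exact test). Weak wild type peaks, the libraries' preparation together or apart, and TXNIP itself stay open.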

How the results depend on the processing

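Equal lists for list members, the comparison of gained with lost regions and the tests of list members against genes able to change were added after seeing the data, and the other settings were planned. Of 758 values under an alternative, 601 kept their direction and their side of the threshold or moved little and 157 changed, of which 4 reversed. All sequence names changed no mean peak number beyond its spread. The cause of the changes was not tested, except that fewer or shorter peaks, a wider window or a single library for a group change counts by construction. Depth is unknown and limits every count of peaks. No paired analysis was possible because a region gained in both numbered pairs is by definition a region gained in both replicates. The heat shock element share with its alternatives and the repeat filter were not run, since no genome was used here.

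At a −log10 q of at least 5, mean peak number was 11044.5 in the second 40 min pair and 8681.5 in the knockout. Replicate overlap was then 90.4% at room temperature, 91.9% in the first 40 min pair, 85.5% in the second and 80.1% in the knockout, the gene-end share was 22.4% in the second pair and 21.2% in the knockout, regions lost from the first to the second pair were 0, and respiratory chain genes lost in the knockout were 4. From the first to the second pair, endoplasmic reticulum chaperones then gained 3, ubiquitin genes 3, and adipocyte, respiratory chain and ribosomal genes 7 each, short of the threshold. A reciprocal overlap of 50% gave 83.4%, 84.9%, 70.7%, 75.1% and 71.9% replicate overlap in the 5 groups (room temperature, first pair, 4 h, second pair, knockout). Equal numbers of top peaks gave 78.8%, 79.2%, 68.3% and 79.0% in the first 4 of these. Peaks of either replicate gave a gene-end share of 23.2% at room temperature, 23.5% at 4 h and 25.2% in the knockout. The 5000 bp window gave 42.3%, 36.6%, 58.3%, 40.5% and 39.0% in the 5 groups, 11 lists past the threshold in the knockout and 5 lost respiratory chain genes. From the first to the second pair it gave 17 gained respiratory chain and 17 immediate early genes, and 6 endoplasmic reticulum and 5 ubiquitin genes, short of the threshold.

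Peaks of 200 bp around summits gave 9 regions lost from room temperature to 40 min, 0 gained from 40 min to 4 h and 14 lost from the first to the second pair. Equal numbers of top peaks gave 94 gained and 57 lost from room temperature to 40 min, 22 and 37 from room temperature to 4 h, 21 and 40 from 40 min to 4 h, 517 and 599 from the second pair to the knockout and 60 and 26 from the first to the second pair. They also gave 3 lost chaperones in each 4 h comparison and 3 lost respiratory chain genes, short of the threshold. From the first to the second pair they gave 1 gained adipocyte gene, and 0 gained endoplasmic reticulum, ubiquitin, respiratory chain, immediate early and ribosomal genes, where under 1 member of each list was expected. Against the first wild type pair, the knockout gained 5630 regions and lost 1, with 0 respiratory chain genes, so gained minus lost regions turned from -1136 to 5629.

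The gene-end share of gained minus that of lost regions, in percent points, was -9.84 in the knockout comparison and turned to 14.02 with equal lists and to 24.5 against the first wild type pair (1 lost region). It was -2.57 at a −log10 q of at least 5 and -2.99 with 200 bp peaks, short of the threshold, and ranged over -11.2 to -1.03 with each replicate left out. From 40 min to 4 h it turned from 79.2 (1 gained region) to -25.2 with equal lists. It passed the threshold at -62.6 from room temperature to 40 min at a −log10 q of at least 5 (4 lost regions) and at -45.9 from room temperature to 4 h with equal lists. In full lists of the latter comparison it ranged over -26.0 to -13.8 with each replicate left out, past the threshold only without 4 h replicate 1.

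With each replicate left out in turn, reproducible regions ranged over 919 to 1269 at room temperature, 1670 to 2287 in the first pair and 123 to 351 at 4 h. Gene-end shares ranged over 23.7% to 26.2% at room temperature, 24.5% to 39.8% at 4 h, 25.6% to 26.4% in the second pair and 23.6% to 25.4% in the knockout. From room temperature to 40 min, 455 to 1058 regions were gained (681 without room temperature replicate 2, 1058 without 40 min replicate 2) and 8 to 93 lost (93 and 32 without room temperature replicates 1 and 2, 41 and 8 without 40 min replicates 1 and 2). From room temperature to 4 h, 4 to 35 were gained (9 without room temperature replicate 2, 35 and 12 without 4 h replicates 1 and 2) and 524 to 951 lost (951 without room temperature replicate 1). From 40 min to 4 h, 1 to 8 were gained (2 without 40 min replicate 2, 5 and 8 without 4 h replicates 1 and 2) and 1152 to 1939 lost (1939 without 40 min replicate 2). In the knockout, 383 to 917 were gained (383 and 643 without wild type replicates 1 and 2, 917 and 899 without knockout replicates 1 and 2) and 2241 to 4020 lost (4020, 2764, 2241 and 2301 in the same order). From the first to the second pair, 8149 to 12202 were gained (12202 without second pair replicate 1) and 1 to 11 lost (7 and 11 without first pair replicates 1 and 2). Lost chaperones ranged over 4 to 7 from room temperature and 5 to 8 from 40 min to 4 h, the highest without 4 h replicate 2. Lost respiratory chain genes ranged over 7 to 9, short of the threshold without wild type replicate 1 and without knockout replicate 1. From the first to the second pair, gained members ranged over 6 to 8 for endoplasmic reticulum chaperones, 5 to 8 for ubiquitin genes, 8 to 11 for adipocyte, 11 to 15 for respiratory chain and immediate early and 9 to 14 for ribosomal genes.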

Other observations

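The loci in this part were chosen after their values were seen, and no explanation was tested for them.

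HSF1 regions at Slc2a1, Akt1 and Pgk1 did not follow the length of the lists, whereas the TXNIP, thioredoxin and glucose uptake list had 9 and 8 members with a peak in the second 40 min pair and the knockout, 1 in each of the room temperature and first 40 min groups and 0 at 4 h. A region inside Slc2a1, which encodes the glucose transporter GLUT1 (chromosome 4, 119132494 to 119133931), was called in all 6 libraries of the room temperature, first 40 min and 4 h groups, with folds of 5.24, 3.91, 3.62, 6.68, 6.89 and 5.71, and in 0 of the 4 libraries with much longer lists. Of the 96 regions called in those 6 libraries, it was the only one missing from the other 4. A region inside Akt1, which encodes a kinase of insulin signalling (chromosome 12, 112658634 to 112659659), was called in 3 libraries, with a fold of 11.7 in room temperature replicate 2, 4.59 in 40 min replicate 1 of the first pair and 21.8 in 4 h replicate 1. The region at Pgk1 was called in room temperature replicate 2, in both 4 h libraries and in the 4 libraries with the longest lists, and in neither library of the first 40 min pair.

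A core of 95 regions held a peak in all 10 libraries, and 46 of them (48.4%, Wilson 95% interval 38.6% to 58.3%) lay near a gene end. Not all were strong. Folds were 1.25 to 1.91 in the regions nearest to Gm2244, 1.35 to 3.65 in that nearest to Esp38 and 1.54 to 4.91 in that nearest to Lrrc4c. No filter on repeats was run, so such regions may not be HSF1 sites. Among the 58 strong regions called in all libraries, Plin3, which encodes a lipid droplet protein, moved from mean place 51.5 at room temperature to 20.5 at 4 h, and Cilk1 from 52.5 to 18. Zfand2a, an arsenite-inducible partner of the proteasome, moved from 22 to 40.3, Ubb, a polyubiquitin gene, from 23.5 to 41.8 and Stip1, which links HSP70 and HSP90, from 12.5 to 24.8.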
